A study of Mus musculus with 60 samples.

How the data were processed

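RNA of male C57BL/6J mice was measured on 54 two-colour arrays, 46 with liver and 8 with heart RNA, and 6 cultures of primary mouse hepatocytes were measured on Affymetrix arrays. The liver groups were sham operation (n = 5 at 6 h and n = 6 at 24 h), myocardial infarction (MI, a lasting coronary occlusion, n = 5 at each time), cardiac ischemia-reperfusion (cardiac I/R, n = 5 at each time), hepatic ischemia-reperfusion (hepatic I/R, n = 5 at each time) and sham operation with hydralazine, a vasodilator that lowers blood pressure (n = 5 at 24 h). The heart arrays covered the risk area (the myocardium supplied by the occluded artery) and the non-risk area after MI and after I/R at 6 h and 24 h, with 1 array for each combination. The hepatocytes were taken 8 h after recombinant osteopontin (n = 3) or mock treatment (n = 3). Samples were grouped by their titles. For MI at 24 h replicate 1 the source name gives cardiac I/R and the title gives MI, and it was placed by its title. The labels disagree on whether RNA was pooled before amplification, so n counts arrays and may not count mice. They also disagree on the Cy3 reference. Per the labels it was RNA of sham mice mixed over time points, but the source named for Cy3 is sham tissue of the array's own time point, and for the hydralazine arrays hydralazine-treated sham liver.

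Each two-colour array held 30000 spots in 48 print blocks, of which 29184 were test spots and 816 controls. Per the file headers, the spot intensity in each channel was the foreground minus the local background, for Cy5 (the sample) and for Cy3 (the reference). The values show that these intensities already carried 1 factor per array between the dyes. For cardiac I/R at 6 h replicate 1 the Cy3 column is a mean where every other array gives a median. Per the file headers and the labels, the authors then scaled each print block, subtracted a negative control level and multiplied Cy5 by a factor per array whose making is not stated. The deposited log2 ratios are the log2 of that Cy5/Cy3 ratio (largest difference 0), left blank where either channel was under 100, and 24.5 to 88.6% of spots had a ratio. The deposited hepatocyte values are linear intensity signals of 45101 probe sets, and the values show that each array was scaled to a 2% trimmed mean of about 500; no label states the software.

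From the scanner intensities, the log2 ratio of sample to reference was computed in limma 3.58.1 (R 4.3.3) with normexp background correction (offset 50) and 1 loess curve per array. Spots with a signal of at least 100 in either channel on at least 5 liver or 4 heart arrays were kept. Gene names came from Entrez identifiers in the files for 21249 spots, from RefSeq accessions for 90 and from the files' own symbols for 532, which can be outdated; 7313 spots had no name. For each of the 15978 symbols the brightest probe was used, and unnamed probes stood for themselves. This left 22452 genes and unnamed probes in liver (15676 named) and 22160 in heart. A limma fit with 1 mean per group over all 46 liver arrays (37 residual degrees of freedom) gave each contrast with its standard error (SE), and p-values were adjusted by Benjamini-Hochberg within each contrast. A gene is said to have risen or fallen at an adjusted p under 0.05. Values after ± beside a difference are SE, and beside a group mean or array measure they are SD. The heart fit had area, injury and time as additive terms (4 residual degrees of freedom). Hepatocyte signals were log2-transformed and quantile-normalized, 64 control probe sets and the lowest 40% by mean signal were left out, and 27022 probe sets were tested with limma. No table pairing these probe sets with genes was used, so neither a choice of probe set per gene nor its alternative was run.

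Genes to name were fixed by rule before the data were examined, as were the comparisons and the gene lists. For each contrast against sham these were the 5 largest increases and the 5 largest decreases among named genes that passed and lay on the same side of the control mean in every treated replicate, and up to 3 members of each list with the smallest adjusted p. Where no gene passed, the 5 named genes with the smallest p were taken, as values only. For direct contrasts the 5 largest changes each way were taken, for single heart arrays the 5 highest and 5 lowest mean ratios with a single sign in all 4 risk areas, and Spp1 (osteopontin) in every contrast. Xist and Y-linked genes are not reported. Some genes that these rules select are not reported here. The 35 lists held 693 member entries, 649 of them on the array. There were 11 marker lists (adipose tissue, cardiomyocytes, cholangiocytes, endothelial cells, erythroid cells, hepatocytes, Kupffer cells and macrophages, lymphocytes and NK cells, neutrophils, pancreas, stellate cells) and 24 others (acute-phase and negative acute-phase proteins, complement and coagulation, cytochrome P450 enzymes, fatty acid oxidation, fatty acid and cholesterol synthesis, bile acids, glucocorticoid and fasting response, male-biased growth hormone-dependent and female-biased genes, heat shock, unfolded protein response, hypoxia, NRF2, p53, IL-6 and STAT3, NF-kB, interferon, immediate-early genes, cytokines and growth factors, extracellular matrix, cell cycle, circadian clock). Lists were scored with camera in limma at a preset correlation of 0.01 between genes, and again with an estimated correlation; p-values were adjusted over the lists of a contrast, and counts of members adjusted over the list alone are given beside those over all genes.

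Overlaps between contrasts sharing sham arrays were set against no-change simulations (100 for covariances, 20 for calls). They were also set against independent lists and fits dividing the sham arrays between contrasts in 10 ways. Group labels were redrawn in 100 random splits per liver contrast, in 33 for heart and in all 10 for the hepatocytes. The fits were tested on simulated data with known changes. For MI at 24 h they recovered 20.6% of changes of 0.5 on the log2 scale, 65.7% of changes of 1 and 100% of changes of 2, with 5 false calls among 132; for the heart they recovered 20.5%, 85% and 98.5%, with 11 false calls among 143. The simulation of the hepatocyte fit was changed after its output was seen, and all its forms are given with that result. Array measures were compared with sham by exact permutation tests (two-sided, 21 tests, Benjamini-Hochberg). Alternatives chosen before the data were examined were the authors' ratios, no background correction, scaling between arrays, other filters, all probes, a replicate block, each array left out in turn and the fit of only the arrays compared. For hydralazine they also held the Cy5 channel alone, and for the hepatocytes an offset of 16 before the log2 and no further normalization. A block for slide or scan date was not run, because the files give none that holds more than 1 group. Chosen after the data were seen were the Cy5 channel alone for the other contrasts, print-tip loess, array weights, the dye trend of each array as a covariate, leaving out arrays with under 50% of spots measured in both channels, and leaving out genes at the top of the Cy5 scale. The number of arrays per group limits the precision. Array measures and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.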

Results

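The series asked how the mouse liver responds to ischemia of the heart, and whether blood-borne factors or blood flow carry the signal, with direct ischemia of the liver and drug-lowered blood pressure as comparison groups. On the liver arrays, 24.8 to 81.5% of test spots had a signal of at least 100 in both channels. Within groups, correlations of the log2 ratio between arrays, taken across genes, which are not independent replicates, ran from −0.09 to 0.29 for sham at 24 h, from 0.32 to 0.44 for MI at 24 h and from 0.44 to 0.53 for hepatic I/R at 6 h. The share of spots with signal in both channels was 75% ± 5.75 (SD, n = 6) in sham livers at 24 h. It was lower after MI (54.5% ± 7.02, n = 5, exact permutation p = 0.00433, adjusted p = 0.0208). After cardiac I/R it was 55.3% ± 11.6 (n = 5, exact permutation p = 0.0108, adjusted p = 0.0253), and after hydralazine 50.7% ± 22.8 (n = 5, exact permutation p = 0.00649, adjusted p = 0.0208). It was 65.6% ± 8.17 after hepatic I/R (n = 5, exact permutation p = 0.0563, adjusted p = 0.0985). At 6 h it was 74.7% ± 4.07 in sham, 58.8% ± 3.79 after cardiac I/R (n = 5, exact permutation p = 0.00794, adjusted p = 0.0208). At that time it was 67.5% ± 6.58 after MI (n = 5, exact permutation p = 0.0714, adjusted p = 0.107) and 75.4% ± 4.55 after hepatic I/R (n = 5, exact permutation p = 0.81, adjusted p = 0.85).

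**Figure D1:**
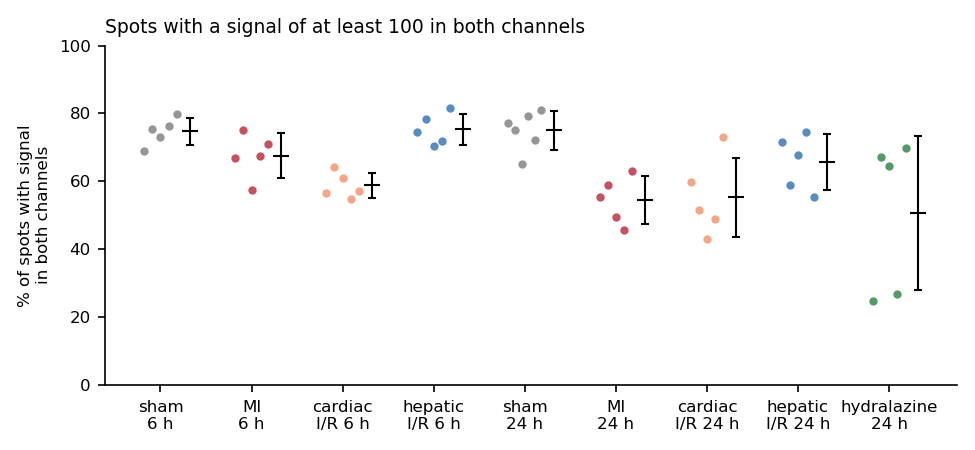
Percent of test spots with a signal of at least 100 in both channels on each liver array (points; bars are mean and SD). Sham arrays at 24 h averaged 75%, MI arrays 54.5%, cardiac I/R arrays 55.3% and hydralazine arrays 50.7%, with hydralazine replicates 1 and 4 at 24.8 and 26.9%.

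In the liver 24 h after MI, acute-phase proteins, which the liver secretes in inflammation, were higher than in sham livers, and genes of fatty acid oxidation, fatty acid synthesis and red cells were lower. Unless another number is given, all 5 of 5 treated arrays of a contrast with sham lay on the stated side of the sham mean. Of 26 acute-phase genes measured, 11 rose (15 rose and 1 fell adjusted over the list alone) and 23 had positive values, with a median log2 change of 0.61 (camera adjusted p = 2.62e-10, and adjusted p = 0.0215 with an estimated correlation). Apcs, encoding serum amyloid P, rose by 1.29 ± 0.19 (adjusted p = 2.77e-05), Lcn2, encoding the iron-siderophore binding protein lipocalin 2, by 0.98 ± 0.16 (adjusted p = 7.13e-05), and Mt1, a metallothionein, by 0.89 ± 0.16 (adjusted p = 4.82e-04). Lcn2 lay within 3% of the highest Cy5 value on all 6 sham arrays and 4 of 5 MI arrays, so the size of its change is not exact. Of the 26 acute-phase genes, 20 reached that top on at least 1 array. Without them the list no longer differed (adjusted p = 0.397). Among the genes that reached the top, the 20 acute-phase genes had higher ratios than the other 1018, with a median of 0.63 against 0.06 and 19 of 20 positive (camera adjusted p = 8.80e-06). Where Cy5 is at its top the ratio can move mainly through Cy3, so this comparison does not by itself show more acute-phase RNA.

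Fatty acid oxidation genes and targets of the lipid sensor PPAR-alpha fell, with 7 of 25 measured members down and none up (2 up and 12 down adjusted over the list alone; median −0.48; camera adjusted p = 6.52e-06, and adjusted p = 0.0621 with an estimated correlation). Acadvl, which starts mitochondrial oxidation of long-chain fatty acids, fell by 2.83 ± 0.25 (adjusted p = 1.31e-09), and Acaa1a, a peroxisomal thiolase, by 1.35 ± 0.21. Of 18 fatty acid synthesis genes 4 fell, among them the desaturases Scd1 (−1.44 ± 0.20) and Fads2 (−1.38 ± 0.15, adjusted p = 2.42e-08). The synthesis list passed with camera (adjusted p = 0.00366) but not with an estimated correlation (adjusted p = 0.17). Of 6 erythroid markers 3 fell (camera adjusted p = 0.00159, and adjusted p = 0.0215 with an estimated correlation). They were the globin genes Hbb-b2 (−1.99 ± 0.22, adjusted p = 3.93e-08) and Hba-a1 (−1.16 ± 0.22) and the heme synthesis gene Alas2 (−0.46 ± 0.13, 4 of 5 arrays). Alas2 lost its call without MI replicate 2, 3 or 4 or sham replicate 1 or 4 (highest adjusted p = 0.103), and the erythroid list lost its call without the globin genes, whose sham values lay at the top of the Cy5 scale (adjusted p = 0.543).

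The largest decreases reported after MI at 24 h were Mael (−3.34 ± 0.34, adjusted p = 8.31e-09), Acadvl, Mat1a, which makes the methyl donor S-adenosylmethionine (−2.71 ± 0.38), and the interferon-induced GTPase Iigp1 (−2.35 ± 0.34). The largest increases were Lasp1 (1.60 ± 0.27), Proser2 (1.56 ± 0.34), Fbxo30 (1.55 ± 0.50), Alkbh5 (adjusted p = 9.63e-04) and Klb, the FGF21 co-receptor beta-klotho (1.51 ± 0.31). Fbxo30 was 0.51 without MI replicate 2, and it lost its call without that array or any of the 6 sham arrays (adjusted p up to 0.240). For Alkbh5 no fold is given, because it was dim on 4 of 5 MI and 5 of 6 sham arrays. The glutathione transferase genes Gsta2 (−2.21 ± 0.23, adjusted p = 1.74e-08) and Gsta1 (−1.87 ± 0.23, adjusted p = 3.65e-07) fell, in an NRF2 target list with 3 members down that did not pass (adjusted p = 0.086). Iigp1 was 1 of 4 interferon-stimulated genes that fell, in a list that did not pass (adjusted p = 0.289). The bile acid enzyme gene Akr1d1 (−1.61 ± 0.31), the fatty acid omega-hydroxylase gene Cyp4f14 (−1.88 ± 0.32), the vascular growth factor gene Vegfa (−1.60 ± 0.17, adjusted p = 1.36e-08) and Serpina6, encoding the corticosteroid carrier (−1.40 ± 0.21), also fell. The fibronectin gene Fn1 (1.35 ± 0.20), the gluconeogenesis gene Pck1 (0.98 ± 0.24) and the complement gene C4b (0.66 ± 0.13) rose. Spp1 was −0.29 ± 0.23 (adjusted p = 0.483).

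In all, 863 genes and unnamed probes rose and 751 fell 24 h after MI, out of 22452 tested. The count was 711 with log ratios scaled between arrays (670 of them among the 1614) and 901 without the arrays under 50% of spots measured in both channels (699 among the 1614). The Cy3 channel moved with these calls. Over the 1614 calls, the median change was 0.71 for the ratio, 0.12 for the Cy5 channel (liver RNA) alone in the direction of the ratio and −0.57 for the Cy3 channel alone, and 974 of 1614 kept their direction in Cy5. The Cy3 level of negative control spots was 928 ± 205 (SD) on the MI arrays and 469 ± 140 on the sham arrays (exact permutation p = 0.00649, adjusted p = 0.0208). In the Cy5 channel alone Mael (−2.62), Acadvl (−1.29), Iigp1 (−1.89), Gsta2 (−1.61), Fn1 (2.12), Pck1 (1.75), C4b (1.71) and Klb (1.05) kept both direction and call. Fads2 (0.12), Scd1 (0.22), Alas2 (0.35) and Alkbh5 (−0.02) turned, and the fatty acid oxidation (adjusted p = 0.987) and synthesis (adjusted p = 0.232) lists pointed the other way.

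**Figure D2:**
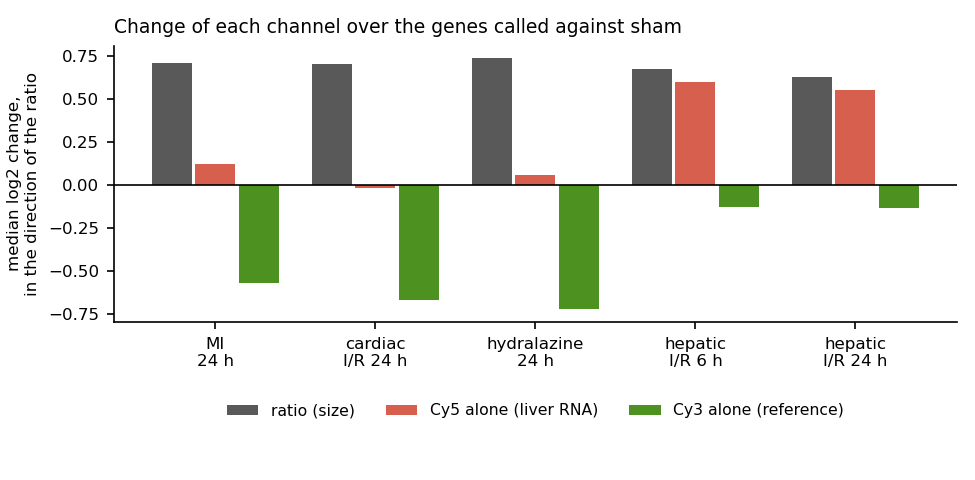
Median log2 change over the genes called against sham, for the ratio (size) and for each channel alone in the direction of the ratio. After MI, cardiac I/R and hydralazine at 24 h the reference channel changed by −0.57, −0.67 and −0.72, and after hepatic I/R at 6 h and 24 h by −0.13 and −0.14.

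In the liver 24 h after cardiac I/R, acute-phase genes were again higher and the same metabolic groups lower in the ratio, with fewer genes passing. In the Cy5 channel alone fatty acid oxidation (adjusted p = 0.0721), fatty acid synthesis (adjusted p = 0.472) and NRF2 targets (adjusted p = 0.213) pointed the other way. Of 26 acute-phase genes 6 rose (14 adjusted over the list alone; camera adjusted p = 1.08e-11, and adjusted p = 0.0186 with an estimated correlation). Among them were Lcn2 (1.01 ± 0.16, adjusted p = 1.44e-04) and the serum amyloid A genes Saa4 (1.00 ± 0.18) and Saa3 (1.17 ± 0.26). Lcn2 lay at the top of the Cy5 scale on all 6 sham arrays and 1 of 5 cardiac I/R arrays. Without the 20 acute-phase genes that reached it the list did not pass (adjusted p = 0.319), and among genes that reached it acute-phase genes had a median of 0.49 against 0.05 for the other 1016, with 19 of 20 positive (camera adjusted p = 9.48e-06). As after MI, the ratios of genes at the top can move mainly through Cy3. Fatty acid synthesis fell with 2 of 18 members down, Scd1 (−0.96 ± 0.20) and the fatty acid synthase gene Fasn (−1.01 ± 0.22; camera adjusted p = 0.00118, and adjusted p = 0.127 with an estimated correlation). Fatty acid oxidation fell with 1 of 25 down (Acaa1a −0.88 ± 0.21; camera adjusted p = 0.0173, and adjusted p = 0.449 with an estimated correlation). NRF2 targets fell with 2 of 16 down (Gsta2 −1.78 ± 0.23, adjusted p = 1.08e-05, and Gsta1 −1.49 ± 0.23; camera adjusted p = 0.0429, and adjusted p = 0.226 with an estimated correlation). Erythroid markers fell with 2 of 6 down (Hbb-b2 −1.86 ± 0.22, adjusted p = 8.32e-07, and Hba-a1 −1.09 ± 0.22; camera adjusted p = 0.0173, and adjusted p = 0.127 with an estimated correlation). Acaa1a lost its call without cardiac I/R replicate 2 or 4 (highest adjusted p = 0.0777). Without genes at the top of the Cy5 scale the oxidation and NRF2 lists no longer passed (adjusted p = 0.179 for each), and the remaining erythroid markers pointed up (adjusted p = 0.973). In Cy5 alone Scd1 (0.31) and Hba-a1 (0.15) lay on the other side of 0, and Lcn2 (−0.0024) had no room to rise.

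The largest increases after cardiac I/R at 24 h were Map7 (1.51 ± 0.22, adjusted p = 3.92e-05), 4933405D12Rik (1.38 ± 0.30), Fam110c (1.29 ± 0.32), Cyba, a subunit of the superoxide-producing NADPH oxidase (1.29 ± 0.14, adjusted p = 4.67e-07), and Fam243 (1.20 ± 0.22). The reported largest decreases were Hbb-b2, Gsta2, Gsta1 and Anxa10 (−1.31 ± 0.29). In Cy5 alone Map7 (−0.46), Fam243 (−0.12) and Anxa10 (0.59) lay on the other side of 0. Fam110c, at 0.86 without sham replicate 4, lost its call without cardiac I/R replicate 2, 3 or 4 or sham replicate 4 (highest adjusted p = 0.0755), and Anxa10 without cardiac I/R replicate 2 or 4 (highest adjusted p = 0.0815). Spp1 was 0.13 (adjusted p = 0.851). In all, 191 genes rose and 124 fell. The count was 25 in the fit of only these and the sham arrays, 134 without cardiac I/R replicate 2, 128 without replicate 4, 198 without sham replicate 5, and 182 without the arrays under 50% of spots measured in both channels. In the direction of the ratio the Cy5 channel changed by a median of −0.02 and the Cy3 channel by −0.67, against 0.70 for the ratio. In Cy5 alone 150 of 315 kept their direction, and 14 kept a call. The Cy3 level of negative control spots was 867 ± 387 (SD) against 469 ± 140 in sham (exact permutation p = 0.0563, adjusted p = 0.0985). After hepatic I/R it was 604 ± 275 (exact permutation p = 0.323, adjusted p = 0.423).

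At 6 h the heart injuries gave few calls in the liver, with lower ratios of Acadvl and Ces3b after each. The contrasts share their sham arrays. Over all genes the covariance of the changes was 0.0305, against 0.0304 simulated with no change and 0.0143 with divided sham arrays. The contrasts shared 5 calls, against 0 simulated, which was near fixed in advance. With divided sham arrays 0 calls were shared, but those fits called only 1.1 and 1.7 genes on average, so that 0 decides nothing. After MI, 8 genes fell and none rose. The 5 named were Mael (−1.77 ± 0.35, adjusted p = 0.0341), Acadvl (−1.50 ± 0.27, adjusted p = 0.00979), the carboxylesterase gene Ces3b (−1.10 ± 0.22, adjusted p = 0.0386), Mesp2 (−0.82 ± 0.14, adjusted p = 0.0089) and Prr29 (−0.68 ± 0.13, adjusted p = 0.0341). After cardiac I/R, 6 rose and 11 fell. Acadvl (−1.48 ± 0.27, adjusted p = 0.0103), Ces3b (−1.25 ± 0.22, adjusted p = 0.0103), Clec4b1 (−0.90 ± 0.19) and Hba-ps4 (−0.64 ± 0.13) were among those that fell. The deubiquitinase gene Usp5 (1.02 ± 0.20, adjusted p = 0.0303), Sec16a (0.83 ± 0.16), Cort (0.56 ± 0.12) and Lrp10 (0.56 ± 0.11) rose. Of the 25 fatty acid oxidation genes 1 fell after MI, where the list did not pass (camera adjusted p = 0.130), and 2 fell after cardiac I/R (camera adjusted p = 0.046, and adjusted p = 0.841 with an estimated correlation). Spp1 was 0.23 after MI and 0.05 after cardiac I/R. In Cy5 alone Lrp10 (−0.51) and Clec4b1 (0.41) turned. Over the calls the Cy3 channel changed by a median of −0.53 after MI and −0.55 after cardiac I/R in the direction of the ratio. The Cy3 level of negative control spots was 973 ± 241 (SD) after cardiac I/R against 454 ± 86.5 in sham (exact permutation p = 0.00794, adjusted p = 0.0208). After MI it was 634 ± 201 (exact permutation p = 0.0794, adjusted p = 0.111), and after hepatic I/R 452 ± 119 (exact permutation p = 0.992, adjusted p = 0.992). At an unadjusted p under 0.05, 1122 and 1824 genes passed after MI and cardiac I/R. Single arrays decided these counts. The MI count fell to 1 without MI replicate 1 or 4, to 3 without MI replicate 2 or sham replicate 2 and to 0 without sham replicate 1 or 5. The cardiac I/R count was 0 without cardiac I/R replicate 1 or 4 or sham replicate 5, 2 without sham replicate 1, 5 without sham replicate 2, 10 without sham replicate 4 and 34 without cardiac I/R replicate 3. Every gene named here lost its call without at least 1 of the arrays just given, with adjusted p up to 0.223 (Cort).

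Both heart injuries called 194 genes in the same direction at 24 h (121 up and 73 down) and 1 in opposite directions. Lists of these sizes drawn independently would share 7.34 up and 4.15 down. Simulations with no change and shared sham arrays shared 0, which was near fixed in advance for every pair given here. Fits with the sham arrays divided between the contrasts shared 40.5 on average (34 to 52). Those fits called only 599.5 and 113 genes on average against 1614 and 315, and fewer for the other pairs too. Part of the fall may be lost calls. The covariance of the changes was 0.0593 against 0.0252 simulated, a difference of 0.0341. After MI and hydralazine 403 genes were shared in the same direction and 8 in opposite directions, against 39.0 up and 27.3 down for independent lists, 0 simulated and 71.4 (59 to 87) with divided sham arrays (covariance difference 0.0417). After MI and hepatic I/R 173 were shared and 87 were opposite, against 24.7 up and 16.3 down, 0 simulated and 47.4 with divided sham arrays (covariance difference −0.0177). Cardiac and hepatic I/R shared 89 and had 4 opposite, against 5.46 up and 2.68 down, 0 simulated and 15.3 with divided sham arrays (covariance difference −0.0049). Cardiac I/R and hydralazine shared 119 and had 3 opposite, against 8.63 up and 4.5 down, 0 simulated and 22.4 with divided sham arrays (covariance difference 0.0273). After hepatic I/R and hydralazine 95 were shared and 57 were opposite, against 29 up and 17.6 down, 0 simulated and 17 with divided sham arrays (covariance difference −0.0172).

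Some genes moved with both heart injuries at 24 h and differed from hepatic I/R in that direction, which was the rule for genes selective for heart injury. There were 98 (67 up and 31 down, 65 of them named). The rule does not ask that hepatic I/R leave a gene unchanged, and 9 of the 98 were called after hepatic I/R, 2 of them in the opposite direction (Scd1 and Tst). The opposite call of Tst was lost without sham or hepatic I/R replicate 2 (highest adjusted p = 0.0717), and Tst after hepatic I/R was −0.48 in Cy5 alone. Among the named ones shown here, chosen after their values were seen, Saa3 rose after MI (1.28) and cardiac I/R (1.17) and was −0.05 after hepatic I/R and −0.24 after hydralazine. Lcn2 rose after both heart injuries (0.98 and 1.01) and also after hepatic I/R (0.54, adjusted p = 0.0335) and hydralazine (0.51, adjusted p = 0.0379). Map7 (1.26 and 1.51) and Cyba (0.91 and 1.29) rose after both and after hydralazine (1.23 and 0.96), with 0.12 and −0.04 after hepatic I/R. Scd1 fell after both heart injuries (−1.44 and −0.96) and hydralazine (−0.96), and rose after hepatic I/R (0.91). Acaa1a fell after both heart injuries (−1.35 and −0.88), with 0.49 after hepatic I/R and −0.60 after hydralazine. Ces1g (−0.93 and −1.08) fell, with 0.32 after hepatic I/R and −0.20 after hydralazine. After hydralazine, 55 of the 98 were called in the same direction, 42 were not called (28 up and 14 down), and Tle5 was called in the opposite direction (0.73, adjusted p = 0.00137). Tle5 itself lost its call after MI without MI replicate 3 or sham replicate 1 or 5, and after cardiac I/R without cardiac I/R replicate 2 or 4 or sham replicate 1 or 5 (highest adjusted p = 0.104). Acaa1a lost its call after cardiac I/R without replicate 2 or 4. The count of 98 was 51 without cardiac I/R replicate 2, 45 without replicate 4, 59 without sham replicate 5, and 37 without the arrays under 50% of spots measured in both channels. In the Cy5 channel alone the 55 genes changed by a median of −0.08 in the direction of the ratio (0.92) and the 42 by −0.14 (0.77), and the Cy3 channel changed by −0.89 and −0.90. In Cy5 alone Map7 (−0.61 and −0.46), Scd1 (0.22 and 0.31), Ces1g (0.18 and 0.07) and Tle5 (0.94 and 0.92) lay on the other side of 0 from the ratio.

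**Figure D3:**
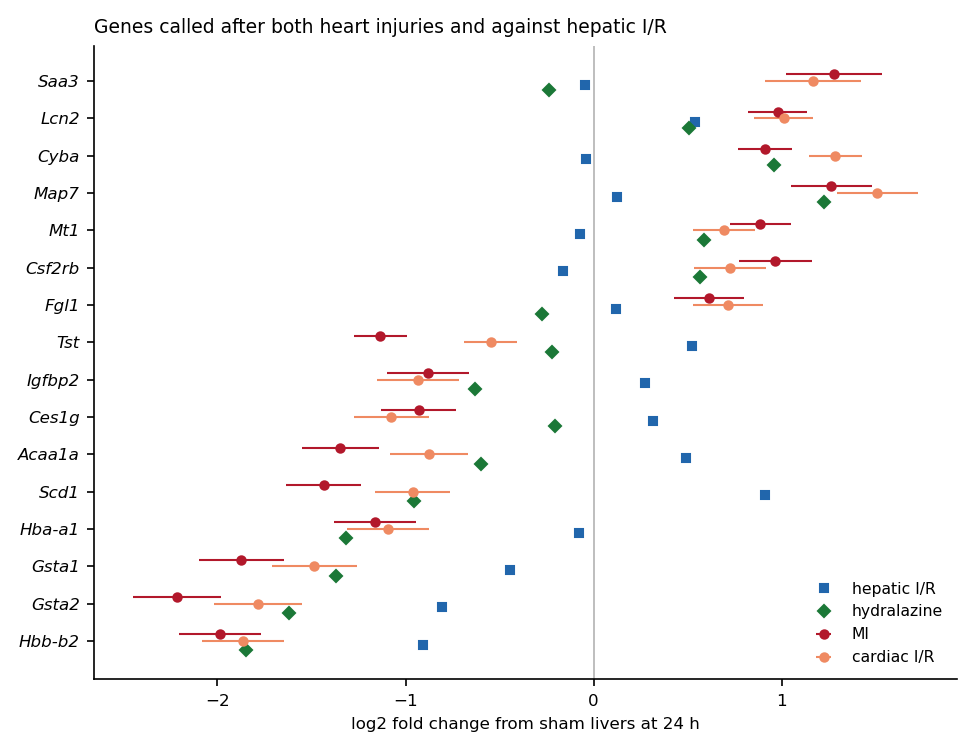
Log2 fold change from sham livers at 24 h of 16 genes called after both heart injuries and against hepatic I/R (circles with SE), with hepatic I/R (squares) and hydralazine (diamonds). Saa3 was 1.28 and 1.17 after the heart injuries and −0.05 after hepatic I/R, and Scd1 was −1.44 and −0.96 against 0.91.

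At 6 h, 5 genes met the same rule, all lower after the heart injuries. With divided sham arrays too few genes were called to test them. The 3 named were Acadvl (0.97 after hepatic I/R), Ces3b (1.15 after hepatic I/R) and Prr29 (−0.08 after hepatic I/R). The count was 0 without MI replicate 1 or 4, cardiac I/R replicate 1 or 4 or sham replicate 1 or 5, 1 without sham replicate 2, 2 without MI replicate 2, 3 without hepatic I/R replicate 2 and 8 without sham replicate 4.

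In livers 6 h after hepatic I/R, genes of several metabolic lists rose. Of 28 cytochrome P450 genes 8 rose (13 adjusted over the list alone; camera adjusted p = 7.58e-12), with Cyp3a25 at 1.53 ± 0.26, Cyp1a2 at 1.14 ± 0.19 and Cyp2d9 at 0.89 ± 0.14. Of 25 fatty acid oxidation genes 8 rose (11 adjusted over the list alone; camera adjusted p = 7.68e-12). They included the transcription factor gene Creb3l3 (1.19 ± 0.17, adjusted p = 1e-05). Of 18 fatty acid synthesis genes 5 rose (camera adjusted p = 1.39e-06), with Scd1 at 1.66 ± 0.21 and Elovl5 at 1.07 ± 0.18. Of 20 bile acid genes 5 rose (10 adjusted over the list alone; camera adjusted p = 9.57e-07), with the phospholipid exporter gene Abcb4 at 1.04 ± 0.16 and the uptake transporter gene Slco1a1 at 1.14 ± 0.23. Of 20 glucocorticoid and fasting genes 4 rose (7 adjusted over the list alone; camera adjusted p = 0.00168), with the gluconeogenesis gene G6pc at 2.19 ± 0.33 (adjusted p = 3.82e-05). Male-biased growth hormone-dependent genes rose with 5 of 21 up (camera adjusted p = 5.84e-04). Of 21 hypoxia-induced genes 4 rose (6 adjusted over the list alone; camera adjusted p = 0.00335), with the kinase gene Pdk1, which shuts pyruvate out of oxidation, at 0.82 ± 0.19. Of 18 IL-6 and STAT3 genes 3 rose (4 adjusted over the list alone; camera adjusted p = 0.00331), with Cebpb at 1.43 ± 0.31 and Pim3 at 1.30 ± 0.28. With an estimated correlation these 8 lists also passed (adjusted p = 3.89e-04 for P450, 0.00264 for fatty acid oxidation, 0.00921 for synthesis, 0.0119 for bile acids, 0.0205 for glucocorticoids, 0.00796 for male-biased, 0.00921 for hypoxia and 0.0117 for IL-6).

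Complement and coagulation genes rose 6 h after hepatic I/R (6 of 34 up and 1 down, 8 and 2 adjusted over the list alone; camera adjusted p = 5.99e-05, and adjusted p = 0.0889 with an estimated correlation). C3, the central complement protein, rose by 1.63 ± 0.20 (adjusted p = 9.93e-07), C8a by 1.41 ± 0.18 and the antiplasmin gene Serpinf2 by 1.37 ± 0.16. Other lists passed at the preset correlation only. These were heat shock (2 of 13 up, 4 adjusted over the list alone; adjusted p = 0.0258, and adjusted p = 0.14 with an estimated correlation) and extracellular matrix genes (3 of 22 up; adjusted p = 0.049, and adjusted p = 0.224 with an estimated correlation). Hepatocyte markers were also higher (2 of 16 up, 4 adjusted over the list alone; adjusted p = 0.0258, and adjusted p = 0.294 with an estimated correlation). The acute-phase list did not pass (1 up and 2 down; adjusted p = 0.199). Its ferrireductase gene Steap4 rose (1.98 ± 0.40), and Saa3 (−1.33 ± 0.27) and Apcs (−1.09 ± 0.20) fell. The largest increases were the protease inhibitor gene Mug1 (2.76 ± 0.53, adjusted p = 7.58e-04), Mat1a (2.21 ± 0.40), G6pc, Ppp1r3c (2.01 ± 0.36) and the carnitine transporter gene Slc22a5 (1.98 ± 0.35). The largest decreases were Rb1cc1, required to start autophagy (−2.52 ± 0.47, adjusted p = 6.0e-04), Ms4a11 (−2.09 ± 0.43), Tes (−1.59 ± 0.30), Hbb-b2 (−1.44 ± 0.23) and Saa3. Hbb-b2 and Apcs lay at the top of the Cy5 scale on all 5 sham arrays and no hepatic I/R array, so the size of their change is not exact. The antioxidant gene Txnrd1 rose by 1.58 ± 0.32, and Spp1 was 0.18 (adjusted p = 0.884). In all, 653 genes rose and 316 fell, and 580 passed without sham replicate 4. The Cy5 channel carried most of the change (median 0.60 in the direction of the ratio, Cy3 −0.13), and 862 of 969 kept their direction in it. The slope of the dye ratio with brightness was −0.20 ± 0.06 (SD, n = 5) against 0.61 ± 0.55 in sham (n = 5, exact permutation p = 0.00794, adjusted p = 0.0208). With it as a covariate 564 genes passed, 499 of them among the 969, and the glucocorticoid, IL-6, heat shock, extracellular matrix and hepatocyte lists did not pass (adjusted p = 0.0855, 0.136, 0.136, 0.317 and 0.573). Without genes at the top of the Cy5 scale the glucocorticoid, heat shock and extracellular matrix lists did not pass (adjusted p = 0.105, 0.125 and 0.0506) and hepatocyte markers pointed down (adjusted p = 0.567).

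At 24 h after hepatic I/R, cholesterol synthesis genes joined those that rose. Of 21 members 7 rose (12 adjusted over the list alone; camera adjusted p = 2.22e-09, and adjusted p = 0.011 with an estimated correlation), with Idi1 at 2.02 ± 0.34, Sc5d at 1.23 ± 0.19 and Acat2 at 0.81 ± 0.11. Fatty acid oxidation genes stayed higher than in sham (9 of 25 up, 13 adjusted over the list alone; camera adjusted p = 1.20e-08, and adjusted p = 0.011 with an estimated correlation). The omega-hydroxylase gene Cyp4a10 was at 1.91 ± 0.36 and Creb3l3 at 1.05 ± 0.16. Male-biased growth hormone-dependent genes also stayed higher (5 of 21 up, 7 adjusted over the list alone, with Cyp4a12a at 0.92 ± 0.21; adjusted p = 2.62e-04, and adjusted p = 0.011 with an estimated correlation). Complement and coagulation genes rose with 10 of 34 up and 1 down (C3 2.16 ± 0.19 and C8a 1.89 ± 0.17, each with adjusted p = 5.43e-10, and Serpinf2 1.47 ± 0.16; camera adjusted p = 1.17e-06, and adjusted p = 0.0635 with an estimated correlation). Unfolded protein response genes rose with 4 of 24 up (6 adjusted over the list alone; camera adjusted p = 1.72e-04, and adjusted p = 0.10 with an estimated correlation). Among them were the disulfide isomerase genes Pdia4 (1.05 ± 0.13, adjusted p = 1.58e-06) and Pdia6 (1.11 ± 0.21). Acute-phase genes rose with 5 of 26 up (8 adjusted over the list alone; Serpina3n 1.21 ± 0.24; camera adjusted p = 2.62e-04, and adjusted p = 0.156 with an estimated correlation).

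The remaining lists that rose 24 h after hepatic I/R did so at the preset correlation only. Of 20 bile acid genes 5 rose (8 up and 1 down adjusted over the list alone; adjusted p = 0.00173, and adjusted p = 0.156 with an estimated correlation), with Akr1d1 at 1.76 ± 0.31. Of 28 cytochrome P450 genes 4 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00223, and adjusted p = 0.125 with an estimated correlation), with Cyp2c37 at 0.92 ± 0.23. Of 18 fatty acid synthesis genes 4 rose (adjusted p = 0.00371, and adjusted p = 0.156 with an estimated correlation), with Fads2 at 0.97 ± 0.15 and Scd1 at 0.91 ± 0.20. Of 16 negative acute-phase genes 3 rose (adjusted p = 0.0257, and adjusted p = 0.326 with an estimated correlation). The largest increases were Mug1 (2.26 ± 0.50, adjusted p = 0.00324), C3, BC013476 (2.11 ± 0.39), Idi1 and Dhdh (1.95 ± 0.40). The largest decreases among genes with a usable signal were Tmem121b (−1.49 ± 0.18, adjusted p = 2.54e-07), Tes (−1.41 ± 0.28) and the p53-induced Pidd1 (−1.32 ± 0.23). Ms4a3 (adjusted p = 6.22e-04) and 4933414I06Rik (adjusted p = 0.0367) also had lower ratios. No fold is given for them, because they were dim on 5 of 5 hepatic I/R arrays and on 6 and 4 of 6 sham arrays, and in Cy5 alone Ms4a3 was on the other side (0.46). The call of 4933414I06Rik was lost without sham replicate 1, 2, 3 or 5 or hepatic I/R replicate 1, 2, 3 or 4 (highest adjusted p = 0.112). Spp1 was −0.02 (adjusted p = 0.988). In all, 642 genes rose and 486 fell. The Cy5 channel changed by a median of 0.55 and the Cy3 channel by −0.14 in the direction of the ratio, and 955 of 1128 kept their direction in Cy5. The slope of the dye ratio was −0.18 ± 0.13 (SD, n = 5) against 0.44 ± 0.30 in sham (exact permutation p = 0.00217, adjusted p = 0.0208). The P450 list did not pass without genes at the top of the Cy5 scale (adjusted p = 0.692) and pointed the other way in Cy5 alone (adjusted p = 0.956). Among genes at the top, whose ratios can move mainly through Cy3, P450 genes had a median of 0.48 with 12 of 14 positive (camera adjusted p = 0.0256). With the dye trend as a covariate the acute-phase and negative acute-phase lists did not pass (adjusted p = 0.0811 and 0.301).

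**Figure D4:**
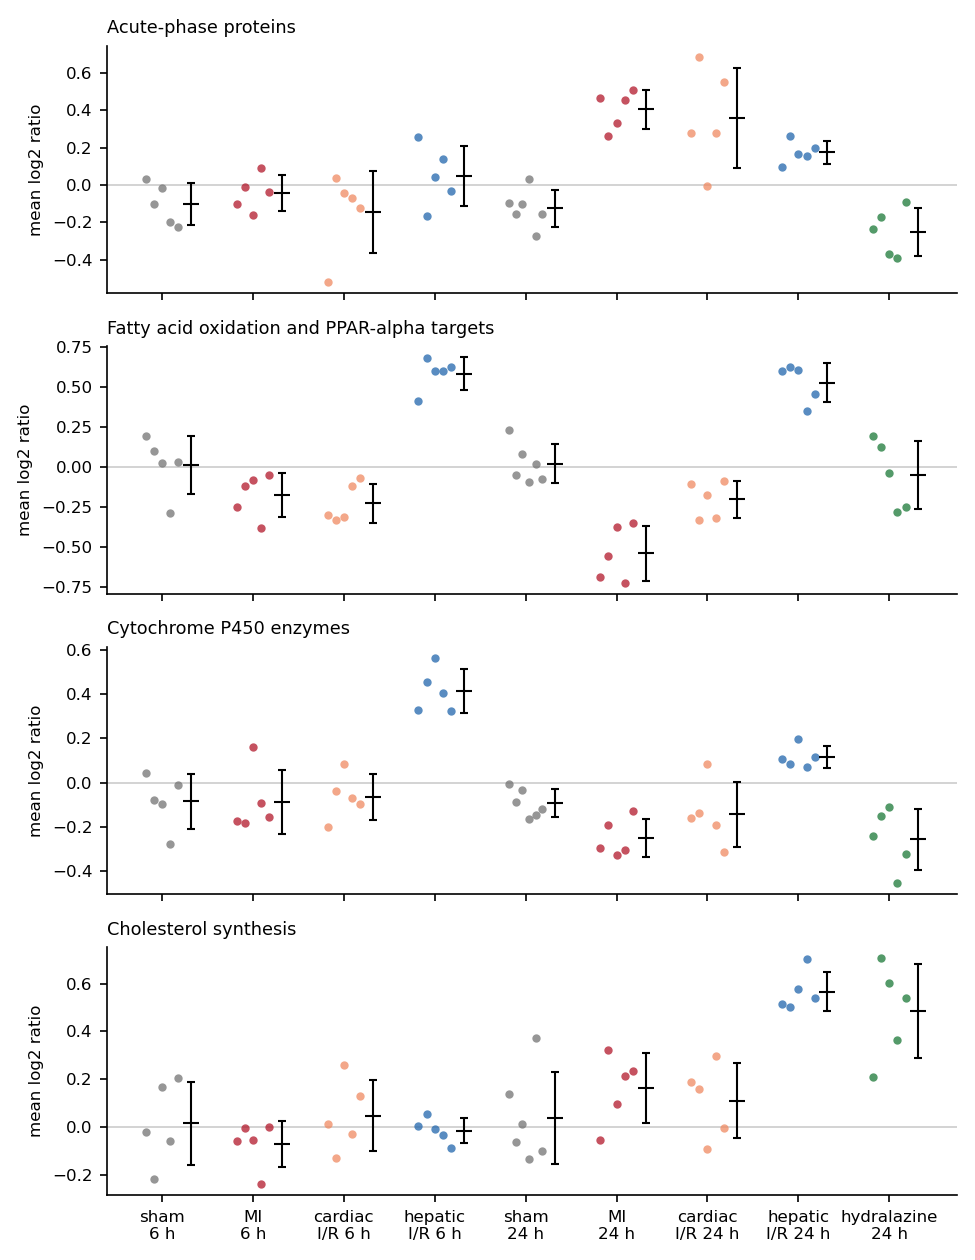
Mean log2 ratio to the sham reference over the genes of 4 lists on each liver array (points; bars are mean and SD). Acute-phase genes were higher after MI and cardiac I/R at 24 h than in sham, and fatty acid oxidation and P450 genes were higher after hepatic I/R at 6 h.

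After hydralazine 1015 liver genes were up and 815 down against sham, a count that fell to 229, 126 and 96 in other fits given below. Whether the Cy3 reference of these arrays was that of the sham arrays is open, since the labels disagree on it. Cholesterol synthesis rose (8 of 21 up, 13 up and 1 down adjusted over the list alone; camera adjusted p = 9.0e-05, and adjusted p = 0.222 with an estimated correlation). Sqle, which makes squalene epoxide on the way to cholesterol, rose by 0.96 ± 0.22. Unfolded protein response genes rose (4 up and 1 down of 24; adjusted p = 0.0304, and adjusted p = 0.478 with an estimated correlation). The chaperone genes Calr (0.98 ± 0.15) and Dnajb9 (0.98 ± 0.24) rose, and Sel1l fell (−1.10 ± 0.25, 4 of 5 arrays; 0.56 in Cy5 alone). Hepatocyte markers fell (4 of 16 down, 1 up and 7 down adjusted over the list alone; adjusted p = 0.0203, and adjusted p = 0.43 with an estimated correlation). Among them were the fatty acid binding protein gene Fabp1 (−1.03 ± 0.24), the urea cycle gene Ass1 (−0.92 ± 0.18) and the transthyretin gene Ttr (−0.71 ± 0.18). All 4 lay at the top of the Cy5 scale. Without such genes the markers pointed up (adjusted p = 0.979). In Cy5 alone, which decides little at its top, they were higher (adjusted p = 0.0236; Fabp1 0.44, Ass1 0.50, Ttr 0.17). Of 28 cytochrome P450 genes 1 rose and 5 fell (adjusted p = 0.037, and adjusted p = 0.43 with an estimated correlation), with Cyp2c70 at −0.76 ± 0.20 and Cyp2b10 at 0.99 ± 0.24 (4 of 5 arrays; −0.015 with the authors' ratios and −0.40 in Cy5 alone). Of 6 erythroid markers 2 fell, Hbb-b2 (−1.85 ± 0.22) and Hba-a1 (−1.32 ± 0.22, and 0.13 in Cy5 alone; adjusted p = 0.0304, and adjusted p = 0.222 with an estimated correlation). The acute-phase list did not pass (4 up and 5 down; adjusted p = 0.534). The fibrinogen genes Fgb (−1.09 ± 0.23) and Fgg (−0.76 ± 0.18) and the protease inhibitor gene Serpina3m (−1.07 ± 0.24), which lay at the top of the Cy5 scale on all sham and hydralazine arrays, had lower ratios among these. With Cy5 at its top in both groups, Cy5 alone (Fgb 0.58, Serpina3m 0.49, Fgg 0.31) decides nothing. Without genes at the top of the Cy5 scale the unfolded protein response, P450 and erythroid lists did not pass (adjusted p = 0.346, 0.903 and 0.971).

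The largest increases after hydralazine were Enpp6 (1.55 ± 0.32), the neutrophil chemokine gene Cxcl1 (1.5 ± 0.40), the cold-induced RNA-binding protein gene Rbm3 (1.42 ± 0.23, adjusted p = 1.52e-04), Ski (1.37 ± 0.32) and Tmub1 (1.36 ± 0.30). The largest decreases among genes with a usable signal were Prl6a1 (−2.24 ± 0.44, and −1.36 without hydralazine replicate 2) and Sap30 (−1.97 ± 0.33, adjusted p = 1.97e-04). Galntl5 (adjusted p = 0.00224), Akap3 (adjusted p = 0.00204) and Epx (adjusted p = 0.00134) also had lower ratios. They were dim on 3, 4 and 5 of 5 hydralazine arrays and on 5, 6 and 6 of 6 sham arrays, so no fold is given for them. Cxcl1 lost its call without sham replicate 6 or hydralazine replicate 5 (highest adjusted p = 0.0798). Spp1 was −0.27 (adjusted p = 0.512). The spread of the hydralazine arrays was 1.86 times the median of the other groups, and their Cy3 level was 1364 ± 845 (SD) against 469 ± 140 (exact permutation p = 0.00649, adjusted p = 0.0208). With array weights 229 genes passed, with log ratios scaled between arrays 126, and in the fit of these arrays and sham alone 96. The Cy5 channel changed by a median of 0.06 in the direction of the ratio and the Cy3 channel by −0.72, and in Cy5 alone all 5 genes with lower ratios named here lay above 0 (Sap30 0.36, Prl6a1 0.73) and Cxcl1 lay below it (−1.53).

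Across the contrasts with sham, 18 of the 35 lists passed in at least 1 at the preset correlation and 11 with an estimated correlation. The other 17 passed in none. Their smallest adjusted p was 0.644 for the cell cycle, 0.552 for the circadian clock, 0.479 for female-biased genes, 0.433 for immediate-early genes, 0.289 for interferon-stimulated genes, 0.552 for NF-kB targets, 0.133 for p53 targets and 0.693 for cytokines and growth factors. Among cell markers it was 0.214 for adipose tissue, 0.477 for cardiomyocytes, 0.248 for cholangiocytes, 0.248 for endothelial cells, 0.276 for Kupffer cells and macrophages, 0.584 for lymphocytes and NK cells, 0.130 for neutrophils, 0.310 for pancreas and 0.0649 for stellate cells.

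Set against each other, the heart injuries differed at 24 h in single genes, and the fatty acid oxidation list did not pass (4 of 25 lower; camera adjusted p = 0.115). Mael (−3.23 ± 0.35, adjusted p = 4.81e-08), Mat1a (−3.17 ± 0.40), Acadvl (−2.78 ± 0.27) and Iigp1 (−2.52 ± 0.36) were lower after MI than after cardiac I/R. These differences were also present in the Cy5 channel alone (−3.57, −3.10, −3.00 and −2.60). Lrrc41 (1.45 ± 0.27, adjusted p = 9.81e-04), Men1 (1.71 ± 0.46), Aebp2 (1.60 ± 0.44), Shcbp1 (adjusted p = 0.0135) and Lrrc40 (1.34 ± 0.32) were higher after MI. The last 4 lost their call without cardiac I/R replicate 2 (highest adjusted p = 0.185), where Men1 was 0.81 and Lrrc40 0.87. Shcbp1 was dim on 3 of 5 MI and 4 of 5 cardiac I/R arrays, so no fold is given, and in Cy5 alone Aebp2 (−0.04) and Lrrc40 (−0.0068) turned. Men1 also lost its call without MI replicate 1, 2 or 5, Aebp2 without cardiac I/R replicate 4 or 5 or MI replicate 1, 2, 3 or 5, and Shcbp1 without MI replicate 3. In all, 203 genes were higher and 313 lower after MI. At 6 h limma called 0 genes between the heart injuries, 1332 of 22452 had an unadjusted p under 0.05, and 1 passed without cardiac I/R replicate 2. The smallest p were those of Pfkfb1 (−0.60), Crot (0.92), Cmip (−0.64), Anapc16 (−0.82) and 4933414I06Rik (adjusted p = 0.386 for each). The last was dim on 4 of 5 MI and 2 of 5 cardiac I/R arrays and is given without a fold.

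The responses to the heart injuries changed between 6 h and 24 h in few genes. After MI 19 genes were higher at 24 h and 32 lower, with the smallest p for Tmbim6 (−1.72 ± 0.22, adjusted p = 1.9e-05), Cep57 (−2.27 ± 0.30), Gabarapl1 (−1.92 ± 0.30), Tmprss6 (−1.83 ± 0.30) and the carbonic anhydrase gene Car3 (−1.80 ± 0.29). For cardiac I/R 16 were higher and 14 lower, with the smallest p for Pex6 at −1.07 ± 0.19, Cyba at 1.16 ± 0.20, Gsta2 at −1.89 ± 0.34, Fasn at −1.66 ± 0.32 and Fitm1 at −0.86 ± 0.17. Acute-phase genes were higher at 24 h than at 6 h after MI (camera adjusted p = 4.39e-09, and adjusted p = 0.0352 with an estimated correlation) and after cardiac I/R (adjusted p = 9.39e-11, and adjusted p = 0.0290 with an estimated correlation). Without genes at the top of the Cy5 scale neither acute-phase difference passed (adjusted p = 0.456 and 0.677). Among the genes at the top acute-phase genes had higher ratios at 24 h after MI (median 0.58, 18 of 20 positive, camera adjusted p = 1.29e-06) and cardiac I/R (0.56, 20 of 21 positive, camera adjusted p = 6.90e-08). Such ratios can move mainly through Cy3, so they do not by themselves show more RNA. Erythroid markers were lower after MI (adjusted p = 0.00256, and adjusted p = 0.0352 with an estimated correlation) but pointed the other way in Cy5 alone (adjusted p = 0.950). The MI count of 51 was 32 and 31 without MI replicate 1 or 3 at 6 h, 25 without MI replicate 3 at 24 h, and 27 without sham replicate 2 or 3 at 6 h. The cardiac I/R count of 30 was 13, 17, 57 and 8 without cardiac I/R replicate 1, 2, 3 or 4 at 6 h, and 14 and 19 without replicate 4 or 5 at 24 h. It was 18, 15 and 16 without sham replicate 1, 2 or 5 at 6 h, and 19 and 17 without sham replicate 2 or 5 at 24 h. Fasn and Fitm1 lost their call without cardiac I/R replicate 4 at 6 h (adjusted p = 0.0702).

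The mean of both heart injuries differed from hepatic I/R in 1785 genes at 6 h (785 higher and 1000 lower) and in 3493 at 24 h (1915 higher and 1578 lower). At 6 h Mug1 (−4.59 ± 0.45, adjusted p = 1.36e-09), Mael (−3.19 ± 0.31), Acadvl (−2.46 ± 0.23) and Canx (−2.34 ± 0.23) were lower after heart injury. Rb1cc1 (2.25 ± 0.41), Ms4a11 (2.11 ± 0.37), Lmtk2 (no fold given; dim on 9 of 10 and 5 of 5 arrays), Pdc (1.05 ± 0.15) and Tes (1.04 ± 0.26) were higher. Tes lost its call without hepatic I/R replicate 1 (adjusted p = 0.0511). At 24 h Cyp4a10 (−3.22 ± 0.33, adjusted p = 2.4e-09), Mug1 (−3.12 ± 0.45), Mael (−2.81 ± 0.31), Mat1a (−2.78 ± 0.35) and Ugt3a2 (−2.48 ± 0.35) were lower. The genes Cxcl1 (2.04 ± 0.37), the airway defence gene Bpifa1 (1.88 ± 0.27), Rb1cc1 (1.56 ± 0.41) and Hoxb7 (1.48 ± 0.33) were higher. So was Ms4a3 (adjusted p = 1.12e-04), for which no fold is given because it was dim on 10 of 10 and 5 of 5 arrays. In Cy5 alone Ms4a3 (−0.65), Hoxb7 (−0.64) and Ugt3a2 (0.75) turned. Without hepatic I/R replicate 2 Rb1cc1 was 0.84 and lost its call at 24 h (adjusted p = 0.0844). Fatty acid oxidation genes were lower after heart injury at 6 h (camera adjusted p = 1.88e-15, and adjusted p = 4.67e-04 with an estimated correlation) and at 24 h (adjusted p = 8.0e-15, and adjusted p = 9.6e-04 with an estimated correlation). So were P450 genes at 6 h (adjusted p = 7.4e-11, and adjusted p = 4.67e-04 with an estimated correlation) and fatty acid synthesis at 24 h (adjusted p = 1.93e-06, and adjusted p = 0.0175 with an estimated correlation). With the dye trend as a covariate, 915 genes passed at 6 h and 1584 at 24 h.

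In the heart itself, the risk areas showed higher values of inflammatory and matrix genes and lower values of heart muscle genes than the non-risk areas. There were no replicates of a combination, and the fit took the 4 combinations of injury and time as replicates of the area difference, which assumes no interaction. limma called 0 of 22160 genes, and 2577 had an unadjusted p under 0.05. The smallest p were those of the neutrophil chemokine gene Cxcl1 (1.44 ± 0.15), the cytokine gene Il6 (1.48 ± 0.17), Ppp1r32 (0.66 ± 0.08), the pentraxin gene Ptx3 (1.19 ± 0.16) and the fatty acid oxidation gene Hadh (−0.93 ± 0.12), each with adjusted p = 0.151. Cxcl1 and Il6 were above the non-risk mean in all 4 risk areas. Values of the lists differed at the preset correlation. Cytokines and growth factors (24 of 30 positive, camera adjusted p = 4.6e-07) and extracellular matrix genes (20 of 22 positive, with Mmp14 at 0.90 and Thbs1 at 0.56; adjusted p = 4.1e-07) were on the higher side. So were NF-kB targets (with Ccl2 at 0.95; adjusted p = 1.5e-04), immediate-early genes (adjusted p = 0.0015), the unfolded protein response (adjusted p = 0.0015) and macrophage markers (adjusted p = 0.0039). Cardiomyocyte markers (1 of 16 positive, with the myoglobin gene Mb at −0.87; adjusted p = 7.6e-07) and fatty acid oxidation genes (with Acadm at −0.77; adjusted p = 2.8e-04) were on the lower side. With an estimated correlation no list passed (smallest adjusted p = 0.306).

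Against the sham reference, the highest mean ratios over the 4 risk areas were those of the natriuretic peptide gene Nppb (2.54), the neutrophil calgranulin gene S100a9 (1.81), Csta2 (1.71), Mapk14 (1.70) and Il6 (1.68). The lowest were those of Cog2 (−1.61, with −1.92 in the non-risk areas), the heart fatty acid binding protein gene Fabp3 (−1.58), Acadvl (−1.52), Slc9a3r2 (−1.46) and Cox7c (−1.38). Spp1, the osteopontin gene and the series' candidate for a factor sent from heart to liver, had log2 ratios of 4.17 in the risk area after I/R and 2.74 after MI at 24 h, and of −0.07 and 0.61 in the non-risk areas. At 6 h the risk areas had 0.13 after I/R and −0.41 after MI. The area difference over all arrays was 1.61 ± 0.62 (adjusted p = 0.380).

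**Figure D5:**
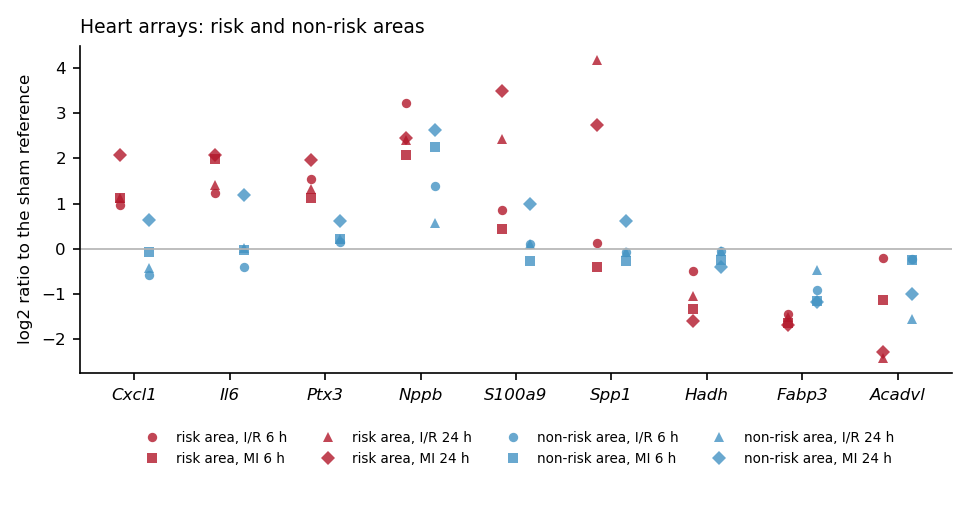
Log2 ratio to the sham reference of 9 genes on the 8 heart arrays (risk areas in red, non-risk areas in blue; 1 array per point). Spp1 reached 4.17 and 2.74 in the risk areas at 24 h and lay between −0.41 and 0.61 on the other 6 arrays.

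Recombinant osteopontin for 8 h gave no called change in hepatocytes. limma called 0 of 27022 probe sets (n = 3 and n = 3), the smallest adjusted p was 0.312, and 4184 had an unadjusted p under 0.05. No gene is named because no table of the genes of these probe sets was used here. Without osteopontin replicate 1, 3037 passed. On the osteopontin arrays the log2 signal of the cre hybridisation controls was 17.7, 19.4 and 20.6, against 15.9, 16.6 and 15.4 on the mock arrays, and that of 18S RNA was 17.2, 18.8 and 19.7 against 15.1, 15.9 and 14.6. In the brightest 25% of probe sets the median SD was 0.767 over the osteopontin arrays and 0.184 over the mock arrays.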

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

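Genes, array measures and list means were searched for a single array apart from the other arrays of its group (a Dixon test), which is met by chance in about 1 in 20 groups. It was met in 53 of 581 groups: 38 of 448 for genes, 3 of 27 for array measures and 12 of 106 for list means. In sham at 24 h, replicate 4 lay apart for Map7 (−1.75), Cyba (−0.84), Nedd9 (−1.29), 4933405D12Rik (−2.60) and Fam110c (−2.50). Other sham arrays at 24 h that lay apart were replicate 2 for Tmub1 (−1.85), replicate 3 for C3 (−0.49), Cxcl1 (1.64) and negative acute-phase proteins (−0.12), and replicate 5 for Abcb11 (0.93). In sham at 6 h these were replicate 4 for G6pc (−1.21), Cyp3a25 (−1.31) and Cebpb (−1.43), replicate 5 for C3 (0.17) and complement genes (0.11), and replicate 1 for Txnrd1 (0.66). After MI at 24 h they were Fbxo30 in replicate 2 (5.94), Scd1 in replicate 3 (−2.35), bile acid genes in replicate 4 (−0.26), and Iigp1 (−1.22), Rb1cc1 (−0.62) and Cyp4a10 (−1.37) in replicate 5. After MI at 6 h they were P450 genes in replicate 3 (0.16) and Cep57 in replicate 4 (0.0074). After cardiac I/R at 24 h they were Igfbp2 in replicate 1 (−0.23), Men1 (−4.57) and Lrrc40 (−2.59) in replicate 2, and Acadvl (0.37) and bile acid genes (−0.10) in replicate 5.

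After cardiac I/R at 6 h, replicate 1 lay apart for the dye trend (1.88) and for the glucocorticoid (−0.29), male-biased (−0.36), IL-6 (−0.057) and acute-phase (−0.52) lists. Replicate 3 did so for Canx (−0.079) and bile acid genes (0.17), and replicate 5 for Sec16a (−0.047) and Spp1 (0.48). After hepatic I/R at 6 h these were fatty acid synthesis in replicate 1 (0.54), Acadvl (0.14) and the Cy3 level (659) in replicate 3, and Ppp1r3c in replicate 4 (1.19). At 24 h they were the dye trend in replicate 1 (−0.41), Rb1cc1 (−4.52), Pdia4 (1.46) and the unfolded protein response (0.57) in replicate 2, and Pidd1 in replicate 3 (−1.08). After hydralazine they were Epx in replicate 1 (−3.91) and Map7 in replicate 4 (1.45). In the heart they were Cxcl1 (2.08) in the risk area and Ptx3 (0.61) in the non-risk area after MI at 24 h, Cog2 in the risk area after I/R at 24 h (−1.02) and Thbs1 in the risk area after I/R at 6 h (1.34).

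Differences between 24 h and 6 h were sought in each heart injury. After MI 51 genes differed, among them Tmbim6 (−1.72), Cep57 (−2.27), Gabarapl1 (−1.92), Tmprss6 (−1.83) and Car3 (−1.80), and the acute-phase and erythroid lists differed (adjusted p = 0.0352 for each with an estimated correlation), the erythroid list in the other direction in Cy5 alone. After cardiac I/R 30 genes differed, among them Pex6 (−1.07), Cyba (1.16), Gsta2 (−1.89), Fasn (−1.66) and Fitm1 (−0.86), and the acute-phase list differed (adjusted p = 0.0290 with an estimated correlation). Signals not used in any contrast were the hybridisation controls of the hepatocyte arrays: the cre spikes were higher by 3.24 and 18S RNA by 3.37 on the log2 scale on the osteopontin arrays, a difference that was not tested.

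The calls in the liver after MI at 24 h were weighed with 2 tests chosen after the result was seen. Over the calls the Cy3 reference channel changed by a median of −0.57 against 0.71 for the ratio. A difference in Cy3 between the arrays, in the reference or otherwise, may thus account for most of the ratio of many genes. Hepatic I/R at 6 h shows that this test could come out otherwise, with −0.13 against 0.67. The dye trend is unlikely to be the whole cause, because 1184 of 1614 calls stayed with it as a covariate. Of the 1614 calls 232 were also made in the Cy5 channel alone. A change in liver RNA is not excluded for the others, because channels taken alone are less exact than ratios. Of the 969 calls after hepatic I/R at 6 h, 348 were kept in Cy5 alone.

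The genes selective for heart injury at 24 h were weighed in 2 sets, those also called after hydralazine and those not, with tests chosen after the result was seen. In the 55 also called, the Cy3 channel changed by −0.89 against 0.92 for the ratio and the Cy5 channel by −0.077. In the 42 not called, the Cy3 channel changed by −0.90 against 0.77 and the Cy5 channel by −0.14. In both sets the ratio thus went with the Cy3 channel, which points to a difference in the reference. The Cy5 medians gave no sign of a change in liver RNA in the direction of the ratio. They cannot exclude one, because both channels share spot and array effects and the genes were picked on the ratio. Cy5 lay on the side of the ratio in 23 of the 55 and 15 of the 42.

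The lack of calls after osteopontin was weighed with 2 tests chosen after the result was seen. The spread over the osteopontin arrays was 4.18 times that over the mock arrays (0.767 against 0.184), which may reflect weak hybridisation of those arrays. The number of arrays decides nothing here. In simulated data of 3 against 3 arrays 39.7% of changes of 2 were called at the spread of the mock arrays, and 60.3% or 38.0% in other forms of the simulation, which was changed after its output was seen. At the spread of the real arrays, 0% of changes of 1, 0% of changes of 2 and 36.1% of changes of 6 were called.

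Random splits of the same arrays gave fewer calls than the real groups in every contrast of liver with sham (100 splits each, the real one the only one as large, so 1 of 100). The real and the highest other counts were 8 and 1 for MI at 6 h, 17 and 2 for cardiac I/R at 6 h, 1614 and 493 for MI at 24 h, and 315 and 138 for cardiac I/R at 24 h. They were 969 and 13 for hepatic I/R at 6 h, 1128 and 297 at 24 h, and 1830 and 829 for hydralazine. The real grouping was also the only one as large for MI against cardiac I/R at 24 h (516 and 117) and the cardiac I/R response over time (30 and 1). So it was for heart injury against hepatic I/R at 6 h (1785 and 135) and 24 h (3493 and 21). With 100 splits the smallest possible share is 1 of 100, so chance is unlikely but not excluded. For the selective genes at 24 h (98 and 0) and 6 h (5 and 0) the splits decide little. Their rule needs calls in several contrasts at once, so 0 in the other splits was near fixed in advance. For the MI response over time 2 of 100 splits were as large, and the highest other count of 309 against 51 may point to a structure of the samples, which was not tested. For MI against cardiac I/R at 6 h (0 and 4; 100 of 100) and the heart areas (0 and 0; 33 of 33) the real count was 0, so every split was as large and the splits decide nothing. The hepatocytes had 10 splits, which are too few (0 and 0; 10 of 10).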

How the results depend on the processing

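Counts of calls that moved by more than 1.5 times, and genes and lists that changed direction, are given by setting; the cause was not tested. With the authors' ratios, the counts were 2 for MI and 44 for cardiac I/R at 6 h, 206 for cardiac I/R at 24 h, 184 and 660 for hepatic I/R at 6 and 24 h, and 3307 for hydralazine. They were 250 for MI against cardiac I/R at 24 h, 902 for heart injury against hepatic I/R at 6 h, 19 for the cardiac I/R response over time, 63 and 2 for the selective genes at 24 and 6 h, and 2 for the heart areas. Cyp2b10 after hydralazine was −0.015. Without background correction, cardiac I/R at 24 h had 574 and the selective genes 158 and 3. With log ratios scaled between arrays, MI had 67 at 6 h and 711 at 24 h, cardiac I/R at 6 h 39, hepatic I/R 1922 and 2063, and hydralazine 126. MI against cardiac I/R at 24 h had 171, heart injury against hepatic I/R at 6 h 2693, the responses over time 9 (MI) and 6 (cardiac I/R), and the selective genes at 24 h 59. With a signal of at least 100 in both channels on every array, MI had 30 and 835, cardiac I/R at 6 h 31, hydralazine 736, MI against cardiac I/R at 24 h 167, heart injury against hepatic I/R at 24 h 1624, and the responses over time 110 and 91. With a replicate block, cardiac I/R at 6 h had 6, its response over time 10, the selective genes at 6 h 2, and the heart areas 1 with a replicate block of injury and time. Replicate numbers did not pair (80 pairs of arrays, correlations from −0.10 to 0.13). The heart areas had 1 with all probes tested. In fits of only the arrays compared, MI at 6 h had 4, cardiac I/R 0 at 6 h and 25 at 24 h, hepatic I/R at 6 h 1689, hydralazine 96, MI against cardiac I/R at 24 h 230 and the selective genes at 6 h 1. With array weights, MI at 6 h had 293, cardiac I/R at 6 h 81, hepatic I/R 2922 and 2702, and hydralazine 229. MI against cardiac I/R at 24 h had 317, heart injury against hepatic I/R 3855 and 5279, the responses over time 296 and 80, and the selective genes at 6 h 23. With the dye trend as a covariate, hepatic I/R at 6 h had 564, hydralazine 1188, heart injury against hepatic I/R 915 and 1584, and the selective genes at 24 h 59. Without arrays under 50% of spots measured in both channels, MI had 4 at 6 h and 901 at 24 h, cardiac I/R at 24 h 182, MI against cardiac I/R at 24 h 253, and the selective genes 37 at 24 h and 1 at 6 h. Without genes at the top of the Cy5 scale, cardiac I/R at 24 h had 173. Print-tip loess and the fit without a filter moved no count this far.

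In the Cy5 channel alone, MI at 6 h had 452 calls, cardiac I/R 1213 at 6 h and 1091 at 24 h, hepatic I/R 3133 and 4608, and hydralazine 1016. MI against cardiac I/R at 24 h had 152, heart injury against hepatic I/R at 24 h 6497, the MI response over time 20, and the selective genes 206 at 24 h and 28 at 6 h. These genes changed direction in it after cardiac I/R at 6 h: Lrp10 (−0.51) and Clec4b1 (0.41). After MI at 24 h they were Alkbh5 (−0.021), Fads2 (0.12), Scd1 (0.22), Alas2 (0.35), Map7 (−0.61), Igfbp2 (0.15), Ces1g (0.18), Csf2rb (−0.36), Nedd9 (−0.39) and Tle5 (0.94). After cardiac I/R at 24 h they were Map7 (−0.46), Fam243 (−0.12), Anxa10 (0.59), Lcn2 (−0.0024), Scd1 (0.31), Hba-a1 (0.15), Igfbp2 (0.28), Ces1g (0.071), Csf2rb (−0.0067), Nedd9 (−0.0375), Tst (0.38) and Tle5 (0.92). After hepatic I/R at 24 h they were Ms4a3 (0.46) and Tst (−0.48). After hydralazine they were Cxcl1 (−1.53), Prl6a1 (0.73), Galntl5 (0.82), Sap30 (0.36), Akap3 (0.28), Epx (0.56), Ass1 (0.50), Fabp1 (0.44), Ttr (0.17), Hba-a1 (0.13), Cyp2b10 (−0.40), Sel1l (0.56), Fgb (0.58), Serpina3m (0.49), Fgg (0.31) and Map7 (−0.21). Between MI and cardiac I/R at 24 h they were Aebp2 (−0.043) and Lrrc40 (−0.0068), and between heart injury and hepatic I/R at 24 h Ms4a3 (−0.65), Hoxb7 (−0.64) and Ugt3a2 (0.75). Of 207 calls of named genes, 77 stayed in Cy5 alone, 83 were lost in the same direction and 47 changed direction. With Cy5 at its top, as for Lcn2 and Fgb, this decides little. Calls lost were 68 of 207 in fits of only the arrays compared, 53 of 190 with the authors' ratios and 44 of 207 with scaled ratios. With an estimated correlation 27 of 66 list calls stayed, with the dye trend as a covariate 51, and in the Cy5 channel alone 29 lists were called, 9 of them among the 66. Of the 66 list calls 17 changed direction in it. They were fatty acid oxidation (adjusted p = 0.987) and synthesis (0.232) after MI at 24 h, and oxidation (0.0721), synthesis (0.472) and NRF2 targets (0.213) after cardiac I/R at 24 h. Others were P450 genes after hepatic I/R at 24 h (0.956) and hepatocyte markers after hydralazine (0.0236). Between heart injury and hepatic I/R at 24 h they were bile acid, P450 and male-biased genes (0.867 each) and complement, macrophage, NRF2 and unfolded protein genes (0.706 each). Over time they were oxidation (0.791) and erythroid markers (0.950) after MI and NRF2 targets after cardiac I/R (0.382). Lists called only in Cy5, in the other direction, were acute-phase genes after cardiac I/R at 6 h (0.0124), negative acute-phase genes after cardiac I/R at 24 h (2.35e-04) and complement genes in the MI response over time (0.00455). Without genes at the top of the Cy5 scale, erythroid markers after cardiac I/R at 24 h (0.973), hepatocyte markers after hepatic I/R at 6 h (0.567) and hydralazine (0.979), and acute-phase genes between heart injury and hepatic I/R at 24 h (0.878) changed direction.

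With each array left out in turn, the counts ran from 0 to 11 for MI and 0 to 34 for cardiac I/R at 6 h, 1103 to 1817 for MI and 128 to 464 for cardiac I/R at 24 h, 580 to 862 and 774 to 1076 for hepatic I/R, and 1352 to 2343 for hydralazine. They ran from 0 to 1 and 397 to 573 for MI against cardiac I/R, 1261 to 1816 and 2636 to 3638 for heart injury against hepatic I/R, 25 to 74 and 8 to 57 for the responses over time, and 45 to 128 and 0 to 8 for the selective genes. They were 0 throughout for the heart and ran from 0 to 3037 for the hepatocytes. Of the 207 calls of named genes 47 were lost at least once and 0 changed direction. A block for slide or scan date, and probe sets chosen per gene, were not run.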

Other observations

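Further genes that met the rule for selective genes at 24 h included Csf2rb, a receptor subunit of blood cell growth factors (0.97 after MI, 0.73 after cardiac I/R, −0.16 after hepatic I/R and 0.57 after hydralazine), and Nedd9 (0.83, 1.08, −0.12 and 0.40). The liver-secreted Fgl1 (0.61, 0.71 on 4 of 5 arrays, 0.12 and −0.27) and the metallothionein Mt1 (0.89, 0.69, −0.07 and 0.59, called after hydralazine with adjusted p = 0.0214) were higher. Igfbp2, which binds insulin-like growth factors (−0.88, −0.93, 0.27 and −0.63), and the thiosulfate sulfurtransferase gene Tst (−1.13, −0.55, 0.52 and −0.22) were lower. In Cy5 alone several lay on the other side of 0 after MI or cardiac I/R: Csf2rb (−0.36 and −0.0067), Nedd9 (−0.39 and −0.0375), Igfbp2 (0.15 and 0.28) and, after cardiac I/R, Tst (0.38, and −0.48 after hepatic I/R). With 1 array left out, Csf2rb lost its call after cardiac I/R without any of its 5 arrays or sham replicate 3, 4 or 5 (highest adjusted p = 0.119, lowest value 0.46, without sham replicate 4). Fgl1 lost it after MI without MI replicate 1, 3, 4 or 5 or sham replicate 1, 2, 3 or 5 (0.0908), and after cardiac I/R without its replicate 1, 2 or 5 or sham replicate 1 to 5 (0.169). Tst lost it after cardiac I/R without its replicate 2, 4 or 5 or sham replicate 1, 4 or 5 (0.126), Igfbp2 without its replicate 2 or 4 or sham replicate 3 or 5 (0.0711), and Mt1 without its replicate 2 or 4 (0.102). Nedd9 lost it after MI without sham replicate 4 (0.0628).

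The osteopontin arrays held fewer dim probe sets than the mock arrays: 5.02 to 19.7% of probe sets lay under 16, against 27.1 to 41.2%. Their correlations with the mock arrays, across probe sets, were 0.836, 0.647 and 0.580, and those among the mock arrays 0.879 to 0.889.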
